A study of Mus musculus with 12 samples.

How the data were processed

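The series holds messenger RNA profiles of 12 mouse lung samples at day 28, 6 labelled WT and 6 labelled Mut. Total RNA was isolated with a column kit, messenger RNA was selected with oligo(dT) beads, and cDNA was primed with random hexamers, per the labels' protocols, which name no step that marks the strand. The labels give the tissue as lung and also speak of primary cells, and they do not say whether each sample is a separate mouse. The deposited count table holds unscaled numbers of reads per gene and library, as seen from its values, which are whole numbers with a different total in each library. The deposited FPKM table holds the same counts divided by the library total and the gene length, which was checked for 28817 genes with at least 5 reads and adds only the gene lengths. The genome build mm10 and limma are named, without a role or a version, per the submitters' processing notes. The aligner, the counting program and the gene annotation were not given in the sources used here.

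The count table has 59136 entries, 54446 with an Ensembl identifier (54409 with a symbol) and 4690 that match no annotated gene, which held between 0.585% and 0.868% of the counts. Symbols, coordinates, GC content and coding sequences were taken from GENCODE M21 (GRCm38, the same assembly as mm10), so that older symbols such as Iars for Iars1 appear. Library totals ran from 17118716 to 24014890 counts. In every library Xist was low (1.46 to 2.92 CPM) and Y-linked genes were expressed (241 to 356 CPM), so sex was the same in both groups.

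Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19004, including 718 of these unannotated entries, of which 16 were called higher and 39 lower. Libraries were scaled by TMM, with factors from 1.0007 to 1.0414 in WT and from 0.9677 to 0.9903 in Mut, so the groups did not overlap. Mut was compared with WT by the robust quasi-likelihood test with genotype as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values are TMM-scaled, and intervals are 95% confidence intervals. The biological coefficient of variation was 17.4%. On unadjusted p-values 5256 genes lay under 0.05.

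44 gene lists were written before the data were examined, with 789 entries, of which 2 had no symbol in the files. The 43 lists with at least 5 tested genes were tested by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, on voom values, and again with an estimated correlation and by fry. Fry was run for a shift in 1 direction, the result given unless stated, and for changes in either direction. The score of a list is the mean log2 CPM of its genes in a library (prior count 0.5) relative to the WT mean. Scores were compared by an exact two-sided permutation test over all splits into 6 and 6, with Benjamini-Hochberg adjustment over the 44 lists. Each list was also adjusted on its own, given as "over the list alone".

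The choice of named genes was fixed before the data were examined. It took Iars1 and Ctsz, the 12 called genes with the largest increase and the 12 with the largest decrease among those of at least 1 CPM in either group (leaving out predicted genes and sex-linked markers), and up to 4 members of each described list with the smallest p. Any member could be named for the surfactant, surfactant clearance, cathepsin and synthetase lists. Genes named outside this rule are stated to be chosen after their values were seen. Some genes that the rule selects are not reported.

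The pipeline was tested on simulated data with the same 19004 genes and 6 libraries per group. It recovered 19 of 50 genes changed 1.5-fold, 40 of 48 changed 2-fold, 45 of 48 changed 3-fold and 44 of 46 changed 4-fold, with 6 false calls among 154. The shifted list was called and 0 of 44 unshifted lists were, by each of the 3 list tests. The simulated genes varied independently and the lists were drawn at random. This therefore does not show how often lists of genes that vary together are called falsely. As a check on the grouping, 100 of the 462 possible splits of the libraries into 6 and 6 were refitted, the real one among them.

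Alternatives set before the data were examined were RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in at least 6 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, removal of sex-linked markers, other thresholds, camera with an estimated correlation, fry, and each library left out in turn. Alternatives added after the data were seen were library totals alone, removal of GC and length trends (18279 genes, 96.19% of those tested), a tissue score as a covariate, removal of the unannotated entries, the 10 libraries with a shared replicate number, and the exact test of list scores. Figures and overlaps of annotated exons were made in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.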

Results

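Messenger RNA was sequenced from 12 mouse lung libraries, all labelled day 28. 6 libraries were labelled WT (replicates 1, 3, 4, 5, 6 and 7) and 6 were labelled Mut (replicates 1, 2, 3, 4, 5 and 7). The Mut genotype was given as Iars1 Tyr148Cys/Arg444*, a cysteine in place of tyrosine 148 and a stop codon in place of arginine 444. Iars1 encodes the cytosolic isoleucyl-tRNA synthetase, the enzyme that loads isoleucine onto its transfer RNA. The title of the series links the mutation to a build-up of lung surfactant and to cathepsin Z, a lysosomal protease encoded by Ctsz. The single comparison, Mut against WT, therefore asked which lung transcripts differed, with Iars1, Ctsz and the surfactant genes first. Each library held between 17118716 and 24014890 counted reads (up to 20119498 in WT and from 18870399 in Mut). Between 34956 and 41142 of the 59136 entries of the count table had at least 1 read. Values below are TMM-scaled CPM as mean ± SD with n = 6 per group, and log2 fold changes are Mut minus WT with their standard error (SE). The labels did not say that each library came from its own mouse, so the p-values measure the spread between these samples, part of which may be technical.

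Iars1 transcript was not lower in the Mut-labelled libraries. Iars1, annotated under the older symbol Iars (ENSMUSG00000037851), is a protein-coding gene on chromosome 13 from 49682100 to 49734267 of mouse build GRCm38. It read 35.6, 45.9, 35.6, 47.5, 46.8 and 58.4 CPM in WT replicates 1, 3, 4, 5, 6 and 7, and 57.1, 48.3, 50.1, 71.6, 61.6 and 41.4 CPM in Mut replicates 1, 2, 3, 4, 5 and 7. The means were 44.9 ± 8.57 CPM in WT and 55.0 ± 10.7 CPM in Mut, a log2 fold change of 0.29 (SE 0.14, 95% confidence interval −0.01 to 0.59). This difference did not pass the threshold (adjusted p = 0.189, edgeR quasi-likelihood test). The Iars1 log2 fold change was 0.19 without Mut replicate 4 (adjusted p = 0.399) and 0.47 with a fat, heart and airway score as a covariate (adjusted p = 0.0876). The genotype label of the 6 Mut samples called them a knockdown, which the Iars1 transcript level did not show. A count per gene adds the transcripts of both alleles and says nothing of the protein. It therefore checks neither the amino acid change nor the stop codon, and the groups are named by their labels throughout.

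Ctsz transcript was lower on average in the Mut-labelled libraries, a difference that did not pass after adjustment over all genes. Ctsz (ENSMUSG00000016256, chromosome 2 from 174427493 to 174439039) read 131 ± 21.2 CPM in WT and 109 ± 13.3 CPM in Mut, a log2 fold change of −0.26 (SE 0.11, 95% confidence interval −0.49 to −0.03, edgeR unadjusted p = 0.0278, adjusted p = 0.129). WT replicates 1, 3, 4, 5, 6 and 7 read 124, 122, 170, 135, 125 and 108 CPM. Mut replicates 1, 2, 3, 4, 5 and 7 read 106, 99.1, 131, 104, 94.9 and 118 CPM, so 4 of the 6 Mut-labelled libraries lay below every WT library. The Ctsz log2 fold change was −0.13 with GC and length trends removed (adjusted p = 0.173) and −0.17 without WT replicate 4 (adjusted p = 0.276). It was called under 1 alternative setting, limma-voom with sample quality weights (−0.29, adjusted p = 0.0197).

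Across the genome, 869 genes were higher and 1010 were lower in the Mut-labelled lungs, of 19004 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). None of the 99 other splits of the libraries that were drawn called any gene. A fold change of at least 1.5 was reached by 337 of the higher and 652 of the lower genes, and a fold change of at least 2 by 121 and 183. In 740 of the 1879 called genes all 6 libraries of one group lay beyond all 6 of the other. Over all tested genes 870 were separated in this way, against 41.1 (0.216%) for groups formed by chance. The balance of higher and lower calls depended on the scaling of the libraries, with 648 higher and 1242 lower under upper-quartile scaling and 518 and 1513 with library totals alone. Limma on log2(FPKM + 1), which changes the test, the filter and the scaling at once, gave 337 and 1242. Leaving out WT replicate 3, 4, 5 or 6 gave 507 higher and 640 lower, 501 and 650, 401 and 556, and 501 and 670 calls. Leaving out Mut replicate 1, 2 or 5 gave 553 and 743, 569 and 607, and 486 and 637. Of the 122 called genes among the 148 examined one by one, 39 lost the call without WT replicate 5, 32 without WT replicate 4, 31 without Mut replicate 5 and 29 without WT replicate 3.

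The 12 largest increases among genes of at least 1 CPM included enzymes and transporters of amino acid and folate metabolism, and the 12 largest decreases included 5 red blood cell genes. Adm2, which encodes the secreted peptide adrenomedullin 2, rose from 0.169 ± 0.0707 to 2.89 ± 1.31 CPM (log2 fold change 4.07, SE 0.39, adjusted p = 3.07e-05). Aldh1l2 and Mthfd2, enzymes of mitochondrial folate metabolism, rose by 3.04 and 2.49 on the log2 scale. Asns, the asparagine synthetase, rose from 18.8 ± 1.32 to 121 ± 25.8 CPM, a 6.43-fold change and the smallest p of any gene (adjusted p = 9.87e-09). Slc7a11, a cystine transporter, and Chac1, which degrades glutathione, each rose by 2.69, and Slc7a5, a transporter of large neutral amino acids, rose by 2.34. Pck1 (3.28, adjusted p = 0.00152), the gluconeogenic enzyme, and Bpifa1 (3.21, adjusted p = 0.0230), a secreted airway protein, rose as well. The last of the 12 largest increases were those of Gp2 (3.14, adjusted p = 0.0141), Fut1 (2.48, adjusted p = 0.00492) and the lipid droplet gene Cidea (2.46, adjusted p = 0.0411). The 12 largest decreases held 4 haemoglobin genes and Alas2, the erythroid enzyme of haem synthesis, described with the blood cell genes below. Fabp1 (−2.60, adjusted p = 0.00106) and Crabp1 (−2.31, adjusted p = 0.00101) were also among them. So were Ppp2r2c (−2.20, adjusted p = 0.000617), Apol11b (−1.79, adjusted p = 0.0133), Syt6 (−1.71, adjusted p = 0.00723) and Mir142b (−1.63, adjusted p = 0.0105). Mir142b overlaps the microRNA gene Mir142 on the opposite strand over 64 exon bases, and strandedness was not given in the sources used here. Reads of the 2 genes may therefore be mixed. With a fat, heart and airway score as a covariate Bpifa1 had a log2 fold change of 1.16 (adjusted p = 0.143) and Gp2 of 1.66 (adjusted p = 0.177), and neither was called. Both calls also ended with no low-count filter (adjusted p = 0.0691 and 0.0647) and with the replicate number as a block (0.0761 and 0.0613), and that of Gp2 by limma-voom (0.0669). The call of Bpifa1 ended without WT replicate 4 or WT replicate 5 (adjusted p up to 0.0580), and that of Cidea held in 4 of the 12 fits that each left out 1 library (adjusted p up to 0.0933). Over all 27 alternative fits Cidea was called in 11, with a log2 fold change as low as 0.72 and an adjusted p up to 0.536, both with the covariate. That covariate contains the scores of the lists that hold Bpifa1 and Cidea, so part of their loss under it is built in. Syt6 and Mir142b lost their calls with the block, and Apol11b with the block, the covariate, no low-count filter, both voom fits and log2(FPKM + 1) (adjusted p up to 0.0814, 0.0795 and 0.0795).

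Targets of the transcription factor ATF4, which cells switch on when uncharged transfer RNA or misfolded protein halts translation (the integrated stress response), rose almost as a block. Of 29 tested genes of the list 25 were higher and 0 were lower in the Mut-labelled libraries (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.97. The 4 members with the smallest p were Asns, Slc7a11, the transcription factor Atf5 (48.2 ± 7.96 to 177 ± 15.4 CPM, log2 fold change 1.88, SE 0.10) and Phgdh, the first enzyme of serine synthesis (10.5 ± 1.39 to 39.7 ± 5.87 CPM, 1.92, SE 0.12). All 6 Mut-labelled libraries had a list score above every WT library (1.29 ± 0.215 against 0 ± 0.0557 on the log2 scale, two-sided exact permutation test, p = 0.00216, the smallest that 6 against 6 libraries can give, adjusted p = 0.0159). By camera with a preset correlation the list was higher than other genes (adjusted p = 1.62e-33). It was the 1 list of 43 to stay so with an estimated correlation (adjusted p = 0.0233). Atf4 itself, chosen after its value was seen, rose by 0.62 (SE 0.16, adjusted p = 0.0255), a call that ended without WT replicate 5 (adjusted p = 0.0504). The 4 members not called, also named after their values were seen, were Pycr1 (0.65, adjusted p = 0.0729), Ddit3 (0.33, adjusted p = 0.0954), Psph (0.14, adjusted p = 0.467) and Cebpb (0.34, adjusted p = 0.531).

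**Figure D1:**
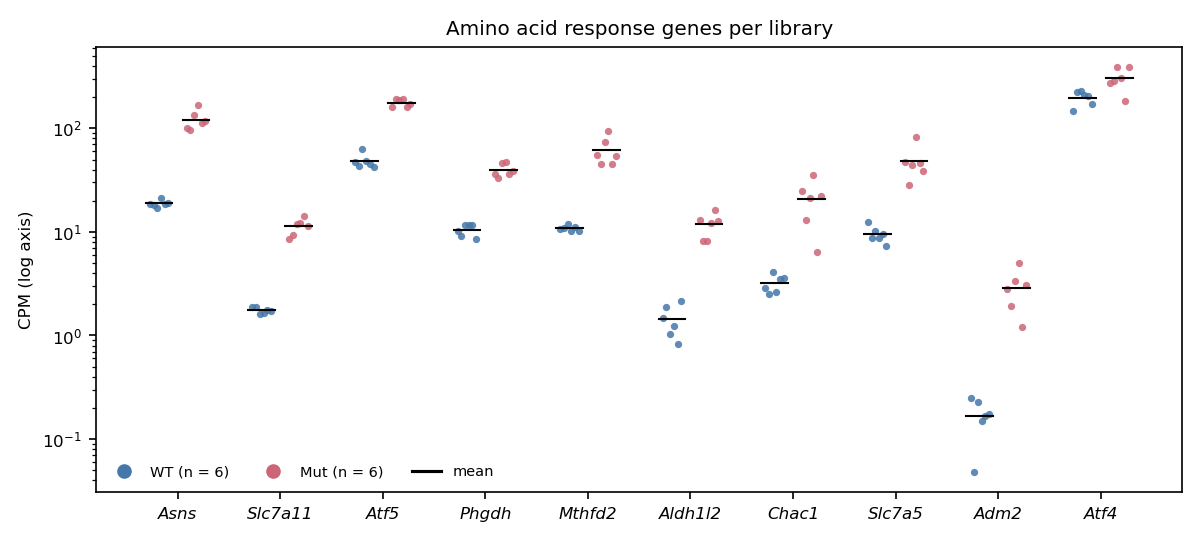
Expression in CPM of 10 genes of the amino acid response in each library, on a log axis, with WT libraries in blue, Mut-labelled libraries in red (n = 6 each) and a bar at each group mean. Asns reads 18.8 CPM on average in WT and 121 CPM in Mut, and the groups do not overlap for any of the genes shown except Atf4.

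Transcripts of 10 cytosolic aminoacyl-tRNA synthetases rose as well, and Iars1 was not among them. Of the 23 tested genes of the list, which also holds 3 scaffold proteins of the synthetase complex, 10 were higher and 0 lower (10 and 0 adjusted over the list alone). Each of the 10 was higher in all 6 Mut-labelled libraries than in every WT library. Under their annotated symbols these were Cars (log2 fold change 1.26, SE 0.11), Mars (0.98, SE 0.12), Yars (0.92, SE 0.11), Aars (0.81, SE 0.09), Nars (0.72, SE 0.07), Gars (0.68, SE 0.09), Sars (0.62, SE 0.08), Tars (0.62, SE 0.08), Eprs (0.42, SE 0.07) and Lars (0.38, SE 0.08), with adjusted p between 1.55e-05 and 0.00887. Among those not called, Wars had a log2 fold change of 0.21 (adjusted p = 0.441), Vars −0.14 (0.329), Hars −0.13 (0.288) and Farsa −0.14 (0.365). Without Mut replicate 4 the log2 fold change of Wars was 0.01. The list score was 0 ± 0.0531 in WT and 0.33 ± 0.0840 in Mut (exact permutation test, adjusted p = 0.0159, all 6 Mut-labelled libraries above every WT library). The camera call with a preset correlation (adjusted p = 3.04e-07) was lost with an estimated correlation (adjusted p = 0.202).

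**Figure D2:**
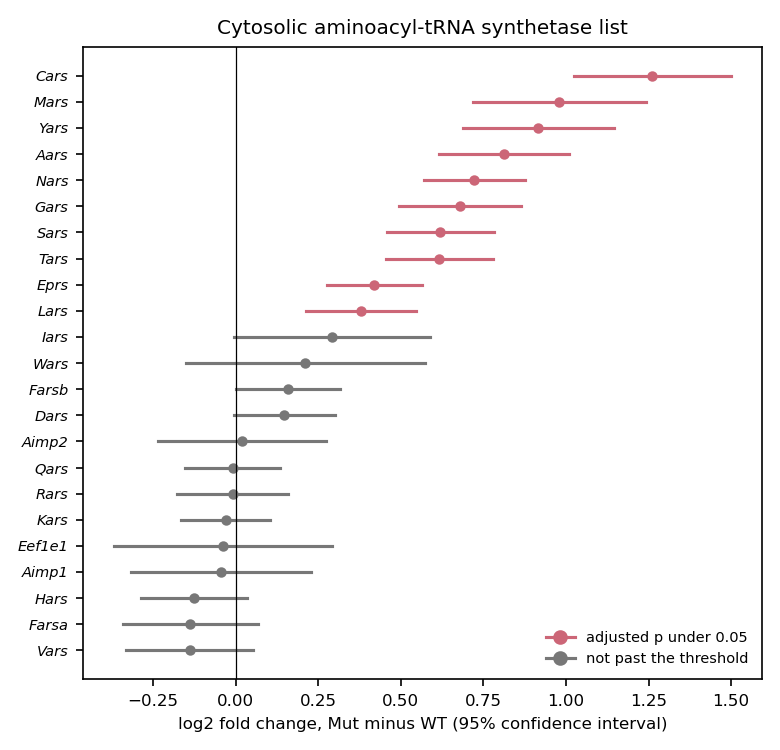
Log2 fold change, Mut minus WT, of each of the 23 tested genes of the cytosolic aminoacyl-tRNA synthetase list, with 95% confidence intervals from the edgeR fit over 6 libraries per group. The 10 genes with an adjusted p under 0.05, in red, run from 0.38 for Lars to 1.26 for Cars, and Iars1 (Iars) lies at 0.29 with an interval that includes 0.

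Lymphocyte genes were lower in the Mut-labelled libraries. All 15 B-cell genes fell (15 adjusted over the list alone), with a median log2 fold change of −1.05. Among them were the antigen receptor genes Cd79b (62.6 ± 17.5 to 27.0 ± 4.84 CPM, −1.22, SE 0.17), Cd79a (−1.19, SE 0.20) and Ighd (−1.15, SE 0.18) and the surface protein gene Cd37 (−1.05, SE 0.15). Of 20 T-cell and natural killer cell genes 14 fell and 0 rose (15 and 0 over the list alone, median −0.80). These included the T-cell receptor constant regions Trbc2 (−0.94, SE 0.14) and Trac (−0.85, SE 0.16), Cd3d (−0.99, SE 0.17) and the kinase gene Lck (−0.84, SE 0.16). Immunoglobulin and plasma cell genes fell in 6 of 12 (7 over the list alone, median −1.07), with Igkc at −1.12, Ighm at −1.02, Iglc1 at −1.44 and Iglc2 at −1.12. Of 17 genes of dendritic cells and MHC class II, the proteins that present antigen, 7 fell (8 over the list alone, median −0.43). Those that fell included Ccr7 (−0.90), Cd74 (−0.61), H2-Eb1 (−0.59) and H2-DMa (−0.63). Another 7 of the 17 had a positive log2 fold change, up to 0.36, and none of these was called. B-cell scores were lower in all 6 Mut-labelled libraries than in every WT library (−1.03 ± 0.292 against 0 ± 0.351, exact permutation test, adjusted p = 0.0159). T-cell, plasma cell and MHC class II scores were so in 5 of 6 (−0.76, −0.90 and −0.31, adjusted p = 0.0238, 0.0317 and 0.0381). The 4 lists were also lower by camera with a preset correlation (adjusted p = 1.62e-15, 4.15e-12, 5.80e-05 and 0.00352). These calls were lost with an estimated correlation (adjusted p = 0.202, 0.202, 0.240 and 0.455). The dendritic cells and MHC class II list alone of the 4 also lost its call by fry (adjusted p = 0.0512) and with a fat, heart and airway score as a covariate (adjusted p = 0.0802), where its median was −0.44. Of 6 tested genes of thymocytes and lymphoid organs 1 fell, Ly6d (−0.89, adjusted p = 0.0304, 4 over the list alone), called in 5 of the 12 fits that each left out 1 library (adjusted p up to 0.0770). That list passed with a preset correlation (median −0.46, adjusted p = 0.0411) and not with an estimated one (adjusted p = 0.225). The call was lost without WT replicate 6 or 7 or Mut replicate 2, 3 or 5 (adjusted p up to 0.0731). It was also lost with upper-quartile scaling, library totals, no low-count filter and the replicate block. The 10 libraries with a shared number and the tissue covariate ended it as well.

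Red blood cell genes and cell cycle genes fell alongside the lymphocyte genes. Of 10 tested erythroid genes 7 fell (10 over the list alone), with a median log2 fold change of −1.72. The haemoglobin genes Hba-a1 and Hbb-bs fell from 936 ± 635 to 161 ± 74.3 CPM and from 1222 ± 683 to 276 ± 145 CPM, log2 fold changes of −2.54 (SE 0.47, adjusted p = 0.00790) and −2.15 (SE 0.47, adjusted p = 0.0165). Their near-identical copies Hba-a2 (−2.79, adjusted p = 0.0177) and Hbb-bt (−2.57, adjusted p = 0.0144) may share reads with them, so the 4 values may not be independent. Alas2 (−1.84, adjusted p = 0.0124) and the red cell membrane gene Slc4a1 (−1.52) also fell. Of 22 cell cycle genes 18 fell and 0 rose (20 and 0 over the list alone, median −0.73), with Aurkb at −1.09, Cdc20 at −0.77, Kif11 at −0.74 and Mcm6 at −0.50. The erythroid score was lower in all 6 Mut-labelled libraries than in every WT library (−1.75 ± 0.668 against 0 ± 0.688, exact permutation test, adjusted p = 0.0159). The cell cycle score was lower in 5 of 6 (−0.77 ± 0.413 against 0 ± 0.166, adjusted p = 0.0238). Camera called both lists with a preset correlation (adjusted p = 2.06e-08 and 5.32e-15) and neither with an estimated one (adjusted p = 0.225 for both).

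Myeloid genes did not fall as one group. Of 14 neutrophil genes 0 fell and 1 rose, the gene of the iron-binding protein lactoferrin, Ltf (2.14, adjusted p = 0.0163), which airway glands also make. Ltf was called in 23 of 28 alternative fits, with a log2 fold change as low as 0.77 and an adjusted p up to 0.0712. Of 18 genes of monocytes and interstitial macrophages 4 fell, Ly6c2 (−0.93), Cx3cr1 (−0.67), Treml4 (−0.72) and Ccr2 (−0.53), and the list did not pass (median −0.10, adjusted p = 0.0549). Ccr2 was called in 2 of the 12 fits that each left out 1 library (adjusted p up to 0.0879). None of 12 tested genes of mast cells, basophils and type 2 inflammation passed (camera adjusted p = 0.708 for that list and 0.325 for neutrophils). Rsad2 was the 1 called gene of 24 interferon response genes (−1.07, adjusted p = 0.0364) and Il1a the 1 of 19 cytokine and acute phase genes (−0.63, adjusted p = 0.0399). They were called in 5 and 4 of those 12 fits (adjusted p up to 0.0862 and 0.0929). Neither list passed (camera adjusted p = 0.592 and 0.708).

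Surfactant protein genes were measured at high levels in every library and none of the 4 was called in the reported fit. Sftpc, the gene of surfactant protein C, read 13552 ± 2699 CPM in WT and 12155 ± 3969 CPM in Mut (log2 fold change −0.16, SE 0.19, adjusted p = 0.622). Sftpb (0.16, SE 0.12, adjusted p = 0.424), Sftpa1 (0.35, SE 0.14, adjusted p = 0.114) and Sftpd (0.13, SE 0.16, adjusted p = 0.622) and the surfactant lipid transporter Abca3 (0.38, SE 0.14, adjusted p = 0.0993) did not pass either. Of 20 genes of surfactant proteins and alveolar type 2 cells 1 rose, the phosphate transporter Slc34a2 (1606 ± 137 to 2340 ± 660 CPM, 0.54, SE 0.15, adjusted p = 0.0332). Its call held in 5 of the 12 fits that left out 1 library (adjusted p up to 0.0746). Mut replicate 7, also the deepest library, had the highest Sftpa1, Sftpb and Lamp3 levels of its group. Without it the log2 fold changes of Sftpa1, Sftpb, Sftpc and Sftpd were 0.20, 0.05, −0.34 and −0.05, and without WT replicate 4 those of Sftpb and Sftpc were 0.24 and −0.05, none of them called. Abca3 was called in 1 of the 12 fits, without Mut replicate 3 (0.48, adjusted p = 0.0228). Over all 28 alternative fits Abca3 was called in 2 and Sftpa1 in 1 (adjusted p = 0.0474), while Sftpb, Sftpc and Sftpd were called in 0. The list had a median log2 fold change of 0.10 and did not pass (camera adjusted p = 0.325, exact permutation test of the score, adjusted p = 0.864).

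**Figure D3:**
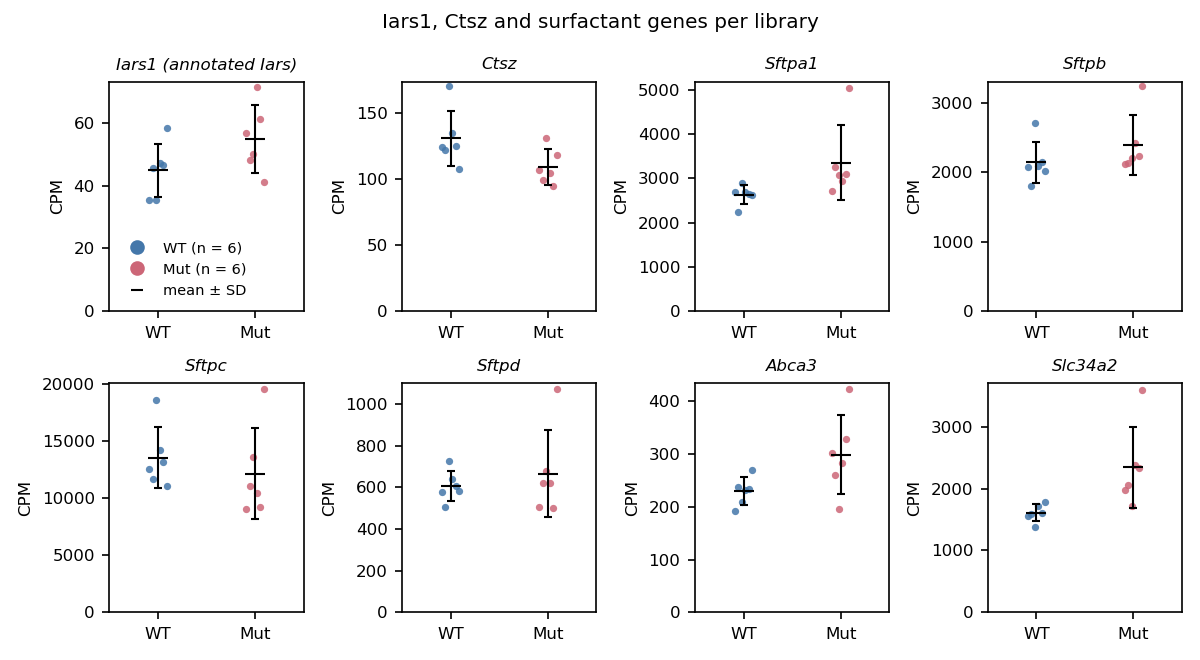
Expression in CPM of Iars1 (annotated Iars), Ctsz and 6 surfactant genes in each library, with WT in blue and Mut-labelled libraries in red (n = 6 each) and bars for the mean ± SD. Of the genes shown Slc34a2 alone passed the test (1606 CPM in WT and 2340 CPM in Mut), and one Mut-labelled library, replicate 7, stands highest for all 6 surfactant genes.

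Genes for the removal of surfactant by macrophages moved singly rather than together. Of 21 tested genes of the list (signalling by GM-CSF, PPARG and lipid export) 1 rose and 1 fell (3 and 3 over the list alone). Npc1, a lysosomal cholesterol transporter, rose from 84.1 ± 12.9 to 124 ± 15.1 CPM (0.57, SE 0.11, adjusted p = 0.00610). Bhlhe41, a transcription factor of alveolar macrophages, fell from 18.1 ± 3.68 to 10.5 ± 2.15 CPM (−0.78, SE 0.16, adjusted p = 0.00748). The receptor genes Csf2ra (−0.33, adjusted p = 0.0540) and Csf2rb (−0.18, adjusted p = 0.397), Pparg (0.21, adjusted p = 0.383), Abca1 (0.51, adjusted p = 0.0660) and Abcg1 (0.07, adjusted p = 0.635) did not pass. Over 28 alternative fits Csf2ra was called in 9 (adjusted p as low as 0.00491), Abca1 in 4 (0.00884) and Csf2rb in 1 (0.0339). Pparg and Abcg1 were called in 0. Csf2rb may share reads with its close copy Csf2rb2. Alveolar macrophage genes went both ways, 4 of 18 higher and 4 lower (6 and 6 over the list alone). Chil3 (238 ± 46.2 to 381 ± 104 CPM, 0.68, adjusted p = 0.0193), and Plet1 (0.54), Lpl (0.88) and Fabp4 (1.57), chosen after their values were seen, were higher. Fabp1 (3.38 ± 1.20 to 0.538 ± 0.360 CPM), Ear2 (−1.07, adjusted p = 0.00475), its close copy Ear1 (−1.53, adjusted p = 0.0189), and Krt79 (−1.05, chosen after its value was seen) were lower. Fabp4 and Lpl are also fat cell genes. Plet1, Lpl and Fabp4 were called in 6, 4 and 2 of the 12 fits that left out 1 library (adjusted p up to 0.0750, 0.0789 and 0.101). Krt79 was lost without WT replicate 4 (adjusted p = 0.0506). Neither the clearance list (camera adjusted p = 0.986) nor the macrophage list (0.943) passed for a shift in 1 direction. For changes in either direction fry called both (adjusted p = 0.00103 and 1.43e-07).

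Among cathepsins and lysosomal genes the clearest change was in Gpnmb, a glycoprotein gene of lysosome-rich macrophages. Gpnmb rose from 8.37 ± 1.58 to 21.3 ± 1.55 CPM (log2 fold change 1.35, SE 0.12, adjusted p = 1.55e-05), higher in all 6 Mut-labelled libraries than in every WT library. Of 30 lysosomal genes 4 rose and 1 fell (6 and 2 over the list alone). The others that rose were Atp6v0d2, a proton pump subunit (0.55, adjusted p = 0.0141), the transcription factor Mitf (0.44, adjusted p = 0.0164) and the peptidase Tpp1 (0.35, adjusted p = 0.00636). Galns fell (−0.33, adjusted p = 0.0474, chosen after its value was seen). Of 16 tested cathepsins and cystatins 1 rose and 1 fell (1 and 1 over the list alone). Ctsw, which cytotoxic lymphocytes express, fell by 0.76 on the log2 scale (SE 0.16, adjusted p = 0.00907), and Ctsf was higher by 0.29 (SE 0.09, adjusted p = 0.0428). Ctsb (0.01, adjusted p = 0.973), Ctsd (0.00, adjusted p = 0.999) and Ctsl (0.24, adjusted p = 0.0705) were not called. Galns and Ctsf were each called in 4 of the 12 fits that left out 1 library (adjusted p of Galns up to 0.117). Neither list passed for a shift in 1 direction (camera adjusted p = 0.525 for lysosome and 0.482 for cathepsins). Both were called by fry for changes in either direction (adjusted p = 1.42e-07 and 0.000447).

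Some fat and airway genes were higher in the Mut-labelled libraries, and no heart gene was called. Of 9 tested adipocyte genes 4 were higher (8 over the list alone, median 1.68), Pck1 (1.24 ± 0.410 to 12.2 ± 9.73 CPM), Plin1 (1.87, adjusted p = 0.0396), Plin4 (1.55, adjusted p = 0.0298) and Cidea. None of the 12 tested cardiac genes was called by edgeR (0 over the list alone). All 12 had a positive log2 fold change (median 0.92), among them Myh6 (168 ± 84.1 to 415 ± 257 CPM, 1.31, adjusted p = 0.0971) and Ryr2 (1.10, adjusted p = 0.0627). Of 17 club and secretory cell genes 3 were higher, Bpifa1 (73.5 ± 69.9 to 677 ± 415 CPM), the mucin Muc5b (1.80, adjusted p = 0.0416) and Scgb3a1 (1.61, adjusted p = 0.0466). Of 16 ciliated cell genes 2 were, Sec14l3 (0.62, adjusted p = 0.0165) and Dnah5 (0.73, adjusted p = 0.0486). None of the 4 list scores passed the exact permutation test (adjusted p = 0.0544 for adipocytes, 0.282 for heart, 0.282 for club cells and 0.422 for ciliated cells). The mean of the fat, heart and airway scores, a measure chosen after the data were seen, was 0 ± 0.534 in WT and 0.96 ± 0.824 in Mut (exact permutation test, unadjusted p = 0.0325). It lay in 5 Mut-labelled libraries above every WT library and in Mut replicate 4, at −0.50, below the WT median. Camera called the adipocyte and cardiac lists with a preset correlation (adjusted p = 0.000845 and 0.00352) and not with an estimated one (adjusted p = 0.455 and 0.701). The club and ciliated lists did not pass (0.0979 and 0.0651). Of the basal and squamous epithelial genes 3 were expressed enough to test and 1, Krt15, was higher (2.22, adjusted p = 0.0303). Plin1, Plin4, Muc5b, Scgb3a1, Dnah5 and Krt15 were called in 5, 7, 4, 2, 1 and 7 of the 12 fits that left out 1 library (adjusted p up to 0.0947, 0.0757, 0.0928, 0.104, 0.115 and 0.0719). With the fat, heart and airway score as a covariate these 6 genes had log2 fold changes of 0.64, 0.71, 0.73, 0.26, 0.16 and 0.31 (adjusted p = 0.345, 0.203, 0.356, 0.602, 0.645 and 0.600), Sec14l3 had 0.52 (0.101), and none of these 7 was called. That covariate contains the scores of the lists that hold all of them but Krt15.

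**Figure D4:**
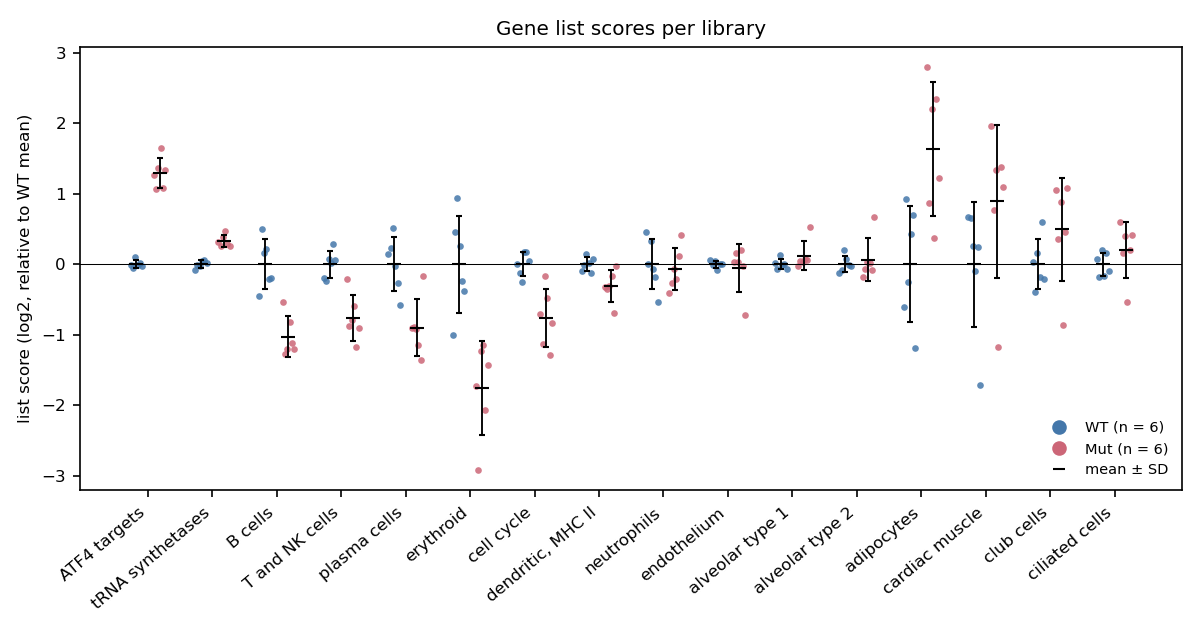
Score of 16 gene lists in each library, the mean log2 expression of the list relative to the WT mean, with WT in blue, Mut-labelled libraries in red (n = 6 each) and bars for the mean ± SD. The ATF4 score lies at 1.29 ± 0.215 in Mut, the B-cell score at −1.03 ± 0.292 and the erythroid score at −1.75 ± 0.668, while the adipocyte and cardiac scores spread most widely.

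Lists of stress and metabolism held few called genes each. Of 22 genes of endoplasmic reticulum chaperones and the unfolded protein response 5 rose (6 over the list alone, median 0.16), Herpud1 (0.61, adjusted p = 0.00647), Dnajc3 (0.39), Dnajb9 (0.37), Atf6 (0.37) and, chosen after its value was seen, Sel1l (0.23). Of 24 autophagy genes 3 rose (3 over the list alone, median 0.09), Optn (0.35), Ulk2 (0.31) and Tax1bp1 (0.27). Of 16 hypoxia genes 3 rose (3 over the list alone, median 0.08), the oxidoreductase Ero1l (0.40), Bnip3 (0.57) and P4ha1 (0.59). Of 15 glucocorticoid response genes 2 rose (6 over the list alone, median 0.62), Klf9 (0.58) and Tsc22d3 (0.67). Of 13 genes of the mitochondrial genome 2 rose (4 over the list alone, median 0.30), mt-Nd5 (0.62) and mt-Cytb (0.42). Camera called these 5 lists with a preset correlation (adjusted p = 0.00352, 0.0241, 0.0394, 5.54e-05 and 0.0156) and none with an estimated one (adjusted p = 0.596, 0.202, 0.202, 0.455 and 0.703). By the exact permutation test of the scores autophagy and hypoxia passed, each with all 6 Mut-labelled libraries above every WT library (differences of 0.11 and 0.17, adjusted p = 0.0159 for both). The other 3 did not (adjusted p = 0.171, 0.0513 and 0.234). The preset call of the unfolded protein response list was lost without Mut replicate 3 (median 0.07, adjusted p = 0.0763). That of autophagy was lost without Mut replicate 4 (0.0670), with library totals (0.0694), in both FPKM fits, with the replicate block and with GC and length trends removed. That of hypoxia was lost without WT replicate 7 (0.0625) or Mut replicate 3 (0.0788), with library totals (0.0527), the stricter filter, sample quality weights and the tissue score as a covariate (0.191, with a median of 0.11). That of the mitochondrial genome was lost without Mut replicate 7 (0.0944), with the block and with the covariate (0.216, with a median of 0.19). Of the genes named here Herpud1, Dnajc3, Ero1l and Optn were called in all 12 fits that left out 1 library. Among the others Dnajb9, Atf6, Sel1l, Bnip3, P4ha1, Ulk2, Tax1bp1, Klf9, Tsc22d3, mt-Nd5 and mt-Cytb were called in 6, 4, 3, 9, 3, 7, 3, 9, 7, 6 and 7 of them (adjusted p up to 0.105).

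The remaining lists gave few or no calls. Of 18 genes of fatty acid and phosphatidylcholine synthesis, the pathways that make the main surfactant lipid, 1 was higher, Acaca (0.32, adjusted p = 0.0411, called in 4 of the 12 fits that left out 1 library, with adjusted p up to 0.0972, and 0 over the list alone). Of 20 cholesterol synthesis genes none was called (camera adjusted p = 0.0651 for both lists). Of 17 NRF2 antioxidant genes 1 rose, Slc7a11, which the ATF4 list also holds (adjusted p = 0.968). Of 16 p53 target genes 1 rose, Ccng1 (0.42, adjusted p = 0.00760), and of 14 smooth muscle and pericyte genes 1, Myocd (1.20, adjusted p = 0.00702). Of 15 genes of transitional alveolar epithelium 1 fell, Mdk (−0.61, adjusted p = 0.0291, called in 6 of those 12 fits, with adjusted p up to 0.0705). None of these lists passed by camera (adjusted p = 0.257, 0.426 and 0.858), and fry called the p53 target list higher (adjusted p = 0.00832). No gene was called among 18 endothelial, 28 cytosolic ribosomal protein, 20 immediate early and heat shock, 10 mesothelial, 9 skeletal muscle and 5 thyroid and parathyroid genes (camera adjusted p = 0.619, 0.247, 0.619, 0.204, 0.325 and 0.395). By camera with a preset correlation 9 of 43 lists were higher and 7 lower in all, a count that 55 of 100 splits of the 12 libraries reached (the real split included). The self-contained test fry called 5 and 6, and 26 lists for changes in either direction. Few genes can carry such a call: it took in the NRF2 list (adjusted p = 8.35e-09), in which Slc7a11 alone was called.

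Some named genes share exon bases with a neighbour, and reads from the shared bases may belong to either gene. Strandedness was not given in the sources used here, and strand would not separate genes on the same strand, such as Aars and Exosc6. Of the 148 genes examined one by one 24 shared at least 100 exon bases with another annotated gene, and 16 of these were called. The widest overlaps among called genes were 1326 bases of Aars with Exosc6, 1280 bases of Bhlhe41 with Gm43909, 1056 bases of Aldh1l2 with D10Wsu102e, 563 bases of Col4a3 with C430014B12Rik, 511 bases of Npc1 with Rmc1, 505 bases of Syt6 with Atg4a-ps and 504 bases of Bnip3 with Gm45507. Alas2 shared 311 bases with Apex2, H2-DMa 360 bases with Brd2 and Cars 211 bases with Gm15580. Among genes not called Ctsl shared 1742 bases with Gm47123 and 395 bases with Gm49230, and Ctsd 808 bases with Gm49369, the last 2 on the same strand. Abca3 shared 914 bases with D330041H03Rik, Ctsb 774 bases with Fdft1, Psph 452 bases with Cct6a and Cebpb 312 bases with Tmem189.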

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

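The tests of B-cell against neutrophil scores, of dilution, and of the fat, heart and airway scores were chosen only after the result was seen, as were the settings with GC and length trends removed, with the tissue covariate and with library totals. A library was singled out where its gap to the nearest library of its group was a large part of the whole range of the group (Dixon's test, 6 libraries). This met 35 of 386 sets of values (9.07%), where chance flags about 1 in 20, or 19.3 sets.

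Mut replicate 7 was the deepest of its group, with a total of 24015000 reads against 18870000 to 19739000 (gap 0.8312 of the range). It had the highest scores for alveolar type 2 cells (0.67 against −0.18 to 0.04, gap 0.7446) and alveolar type 1 cells (0.53 against −0.03 to 0.07, gap 0.823) and the lowest for endothelium (−0.73 against −0.03 to 0.20, gap 0.7502). On the log2 CPM scale its Sftpa1 read 12.30 against 11.41 to 11.68 (gap 0.7001) and Sftpb 11.66 against 11.05 to 11.24 (0.692). Lamp3 was also highest (gap 0.7904), as was Ear2 at 4.94 against 3.82 to 4.15 (0.7056), while Cry1 was lowest at 4.95 against 5.61 to 5.88 (0.7087).

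Mut replicate 4 was lowest of its group for the club cell score (−0.87 against 0.36 to 1.08, gap 0.6288), the hypoxia score (0.05 against 0.17 to 0.24, gap 0.6294), Bpifa1 (log2 CPM 5.40 against 8.55 to 10.26, gap 0.6479) and Scgb3a1 (6.10 against 8.35 to 9.46, gap 0.6682). It was highest for Nars (7.77 against 7.43 to 7.55, gap 0.6375) and Wars (8.04 against 7.09 to 7.34, gap 0.7351). Mut replicate 1 was highest for Ighd (5.92 against 4.95 to 5.21, gap 0.7383).

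WT replicate 1 was lowest of its group for the cholesterol synthesis score (−0.36 against 0.00 to 0.12, gap 0.7594), Syt6 (log2 CPM −0.38 against 1.61 to 2.28, gap 0.748), Pycr1 (1.30 against 1.80 to 2.10, gap 0.6279) and Nr1d1 (log2 CPM 5.80, gap 0.797). It was highest for the p53 target score (gap 0.6918), Abca1 (7.23 against 6.46 to 6.70, gap 0.6905) and Bnip3 (6.01 against 5.24 to 5.46, gap 0.7164). WT replicate 4 was highest for Atf5 (others 5.41 to 5.60, gap 0.6877), Pparg (3.34 against 2.94 to 3.07, gap 0.6735), Cd74 (10.23 against 9.80 to 9.96, gap 0.6316), H2-Eb1 (8.18 against 7.70 to 7.81, gap 0.7791) and H2-DMa (5.62 against 4.82 to 5.09, gap 0.6616). It was lowest for Nars (6.69 against 6.83 to 6.91, gap 0.6406), Tpp1 (6.89 against 7.05 to 7.14, gap 0.6338), Ero1l (5.27 against 5.63 to 5.79, gap 0.6966) and Ulk2 (6.53 against 6.82 to 6.96, gap 0.6833). WT replicate 3 was lowest for Adm2 (−3.76 against −2.52 to −1.87, gap 0.6544) and Sftpa1 (11.13 against 11.36 to 11.50, gap 0.6272), and WT replicate 7 for the cardiac score (−1.71 against −0.10 to 0.66, gap 0.6781).

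Splits of the 12 libraries argue against chance as the source of the called genes: of 100 splits, 1 reached 1879 calls, the real one, and the highest other called 0. For the number of lists chance cannot be excluded, as 55 of 100 splits reached 16 lists and the highest other reached 27, and with an estimated correlation the real split called 1 list, as did 4 others.

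The rise of ATF4 targets held where technical sources were removed. The median of the list was 1.01 with GC and length trends removed (25 genes called), 1.04 with the fat, heart and airway score as a covariate (24 called), and at least 0.91 under 4 scalings. These values argue against base composition, differing shares of fat, heart and airway tissue, and scaling as its source. Genotype is the difference between the groups that the labels name, but batch and hour of sampling were not given and could not be tested. Whether the signal starts from uncharged transfer RNA or from another stress stays open.

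The fall of lymphocyte genes was set against less blood left in the Mut-labelled lungs, dilution by other tissue, and scaling. B-cell scores fell relative to neutrophil scores (−0.96, exact permutation test, p = 0.0130). For the lymphocyte part this argues against a loss of blood that lowers both alike. Neutrophils were the only blood cells set against B cells. Of 18 genes of monocytes and interstitial macrophages 4 fell, 0 rose and 14 were not called, so less blood is not excluded. The mean of the endothelial and alveolar scores did not fall (0.0406, exact permutation test, p = 0.344), which argues against dilution. By list the difference was −0.06 for endothelium, 0.12 for alveolar type 1 and 0.06 for alveolar type 2 cells, against −1.03 for B cells. Mut replicate 7 stood apart with an endothelial score of −0.73. The B-cell median was −1.05 or lower under 4 scalings. For the erythroid part less blood stays open. Erythroid and B-cell scores had a Pearson correlation of 0.839 within WT and 0.318 within Mut (exact permutation p = 0.0417 and 0.535). By ranks the correlations were 0.771 and 0.371 (exact permutation p = 0.103 and 0.497). Without the 2 of 6 libraries per group farthest from the median erythroid score the Pearson values were 0.980 and −0.552, which rest on few libraries.

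Fat, heart and airway scores moved together within groups (mean correlation 0.572, permutation p = 0.0025), as differing shares of these tissues in the samples could produce. By ranks over all libraries the mean correlation was 0.438 (permutation p = 0.0142). The correlation fell to 0.0516 without the 2 libraries per group farthest from their group's median in the mean of these scores. Leaving out the extremes of the same scores favours such a fall. It therefore does not settle whether the correlation rests on those libraries. A rise in every Mut-labelled library was not seen, as replicate 4 lay at −0.50 in the mean of the scores, below the WT median. The other 5 lay above every WT library, and whether genotype contributed to the rise in those 5 stays open.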

How the results depend on the processing

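Library totals alone, GC and length removal, the tissue covariate, removal of unannotated entries, the 10 libraries with a shared number and the exact test of list scores were chosen only after results were seen, and the other alternatives were set beforehand. No log2 fold change of the 113 called genes followed through every alternative changed sign. All 113 stayed called with DESeq2, RLE scaling, removal of unannotated entries and removal of sex-linked markers, 108 with upper-quartile scaling, 106 with GC and length trends removed, 105 with sample quality weights, 103 with library totals, 100 with limma-voom, 84 with no low-count filter, 71 with the 10 libraries of shared number, 65 with the tissue covariate and 35 with the replicate block. The stricter filter kept 109 of 109 tested, and the FPKM fits kept 83 and 84 of 109. Genes higher in Mut numbered 869 in the reported fit and 518 with library totals, 1312 with DESeq2, 2201 with sample quality weights, 337 on log2(FPKM + 1), 331 on log2(FPKM + 0.1), 362 with the tissue covariate, 337 with a fold of at least 1.5 and 1645 at an adjusted p under 0.1. Genes lower numbered 1010 in the reported fit and 2151 with sample quality weights, 493 with the covariate, 652 with a fold of at least 1.5 and 1678 at an adjusted p under 0.1. Leaving out 1 library gave between 401 and 1163 higher and between 556 and 1205 lower. The cause of these moves was not tested, except that the other thresholds change counts by construction. Of the 122 called genes among the 148 examined one by one, 82 stayed called in all 12 fits without 1 library.

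The replicate numbers did not pair the libraries: of 5 shared numbers 2 correlated above 0.1 (−0.14 to 0.11), and 1 correlated best with its own number. As a block they gave 85 genes higher and 41 lower, with 10 libraries, and those 10 libraries without the block gave 271 and 355, so part of the loss comes from fewer samples. Ctsz passed with sample quality weights (−0.29, adjusted p = 0.0197), and the cause was not tested. Lists called higher numbered 9 in the reported fit and 15 with no low-count filter, 1 with an estimated correlation, 5 by fry and 4 by the exact permutation test of scores, and 7 to 12 without 1 library. Lists called lower numbered 7, with 0 under an estimated correlation and 6 to 10 without 1 library. The cardiac list turned to −0.27 with the covariate, which contains that score. Sex as a covariate was not run, as all 12 libraries had the same Xist and Y-linked pattern. In simulated data 19 of 50 changes of 1.5-fold and 40 of 48 of 2-fold were recovered. Depth was not varied.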

Other observations

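The tests of Pck1, Iars1 alleles and kidney genes given here were chosen only after the result was seen. Clock genes changed in both directions. Of 15 tested circadian genes 5 were higher and 1 lower in the Mut-labelled libraries (7 and 2 adjusted over the list alone). The list did not pass for a shift in 1 direction (median 0.02, camera adjusted p = 0.146, exact permutation test of the score, adjusted p = 0.0513). It passed by fry for changes in either direction (adjusted p = 0.000691). Nfil3, a repressor of clock output genes, rose by 1.13 (adjusted p = 0.00342), as did the activator Clock (0.34, adjusted p = 0.0175), Cry1 (0.64, adjusted p = 0.0300), Per2 (0.56, adjusted p = 0.0388) and, chosen after its value was seen, Npas2 (0.91, adjusted p = 0.0426). Nr1d1, which peaks by day and was likewise chosen after its value was seen, was lower (−0.92, adjusted p = 0.0399), with 263 exon bases shared with Thra. Nfil3 and Clock were called in all 12 fits that left out 1 library, and Cry1, Per2, Npas2 and Nr1d1 in 7, 4, 4 and 3 (adjusted p up to 0.0719, 0.0856, 0.0975 and 0.0940). The hour of sampling was not given in the sources used here.

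Matrix genes shifted in both directions. Of 26 tested genes of extracellular matrix and fibroblasts 3 were higher and 1 lower (4 and 2 over the list alone), with a median of −0.05 (camera adjusted p = 0.784). Lox, which cross-links collagen and elastin, rose by 0.74 (adjusted p = 0.00719), with Pdgfra (0.45, adjusted p = 0.0258) and Dcn (0.61, adjusted p = 0.0269), while elastin itself, Eln, was lower at 723 against 1185 CPM (−0.71, adjusted p = 0.0491). Pdgfra, Dcn and Eln were called in 6, 6 and 4 of the 12 fits that left out 1 library (adjusted p up to 0.0635, 0.0618 and 0.116). Of 15 alveolar type 1 genes 2 rose (4 over the list alone), the basement membrane collagen Col4a3 (0.87, adjusted p = 0.00569) and Clic5 (0.49, adjusted p = 0.0157), and the list did not pass (median 0.07, camera adjusted p = 0.0979).

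Pck1 was tested against the fat content of the samples. Its log2 CPM minus the adipocyte score computed without it was higher in Mut by 1.56 (exact permutation test, p = 0.00217), but Pck1 was picked as the highest gene of that list, which favours a positive difference. That difference alone therefore does not settle the point. With the fat, heart and airway score as a covariate Pck1 still rose by 2.08 (edgeR adjusted p = 0.00188). The adipocyte list fell to a median of 0.43, but its score, with Pck1 in it, is part of that covariate. The fall of the list is therefore built in. Mut replicate 4, with a fat score of 0.37 within the WT range of −1.19 to 0.92, read 3.19 CPM of Pck1 against at most 1.78 CPM in WT. The rise of Pck1 with the covariate and its level in Mut replicate 4 argue against fat carry-over as the only source of the rise. The synthetases were tested against a rise of all synthetase genes: the 17 mitochondrial synthetases had a median log2 fold change of 0.064 with none called, against 0.21 for the cytosolic list. Isoleucine codons were tested on the idea that transcripts rich in them fall when their synthetase is impaired. Across 14558 coding genes the Spearman correlation of the log2 fold change with the isoleucine share was 0.0389, a strength reached in 64 of 100 splits of the libraries, so no such fall was seen.

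The Iars1 transcript might hide a loss of the stop-codon allele behind induction by ATF4. Iars1 lay 0.41 below the median of the 10 synthetases called higher (−0.41, with that median at 0.70), but those 10 were selected for being called, which favours a value below them. Against the whole cytosolic list, with a median of 0.21, Iars1 lay higher at 0.29. The idea stays open, as reads were not split by allele. Kidney genes were detected at low levels in some libraries, with Kap up to 28.5 CPM and Slc34a1 up to 5.63 CPM in Mut replicate 2 and Umod up to 3.55 CPM in WT replicate 4. The mean correlation of the 9 detected kidney genes over the libraries was 0.464. Kap, Umod, Slc6a18 and Slc12a1 split the libraries alike. They were higher in WT replicates 4, 5, 6 and 7 and Mut replicates 2 and 7 than in every other library. Kap read at least 3.498 CPM there and at most 0.608 CPM elsewhere. Slc12a3, Slc34a1, Miox, Slc22a12 and Slc22a6 did not split this way. For the genes that did, the split goes with a common source, which was not identified. The split crossed both groups, with more WT than Mut libraries high, and batch was not given.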
